A study of Gallus gallus with 5 samples.

How the data were processed

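Single-cell RNA sequencing with the 10x Chromium v3.1 chemistry, which reads the 3′ ends of polyadenylated transcripts, was applied to cells of the chick embryonic gut in 5 samples. The labels give 5 groups with 1 sample each: midgut at E14, hindgut at E14, midgut at E15 carrying an empty vector, hindgut at E15, and midgut at E15 carrying an inducible HOXD13 vector. Per the labels' protocols, gut pieces were pooled by condition before dissociation, and the E15 midgut cells were sorted for both vector fluorophores. Cell Ranger 7.1.0 and Seurat are named in the submitters' processing notes.

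The files analysed here are 2 gene annotations in GTF form that the authors deposited for the whole series. They hold feature coordinates in bases, counted from 1, and no measurement of any sample. Counts per cell, cluster labels and sequencing depth were therefore not analysed here, and none of the expression comparisons that the design implies was computed. The records of the chicken genome name NCBI RefSeq as their source, per the files' own source column. The genome build appears only as the deposited annotations' label gg6a. Which sample was counted with which annotation is not given in the sources used here.

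Records of the annotations were compared line by line. Every gene symbol was reduced to its transcripts, exons, coding length with the stop codon, and 3′ UTR length. A gene's 3′ UTR length was the longest over its coding transcripts, and 0 where none was annotated. The chicken records carry no biotype, so a gene with a coding sequence was called coding. Genes were called overlapping when they shared at least 1 exonic base on the same strand, because Cell Ranger counts only reads that can be given to a single gene. Whether intronic reads were counted is not given in the sources used here, and overlap of gene bodies was an alternative. The annotation with the HOXD13 vector was used throughout, and the annotation with EGFP was an alternative.

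Before the data were examined, 14 lists with 209 genes were fixed. They covered the Hox genes, TGF-beta, BMP, Hedgehog and Wnt signalling, extracellular matrix, and markers of gut mesenchyme, smooth muscle, enteric neurons and glia, interstitial cells of Cajal, epithelium, endothelium, blood and immune cells, and mesothelium. The rule for naming genes covered all Hox genes, all listed genes that were absent, all with a same-strand exon overlap, and the 2 longest and 2 shortest 3′ UTRs of each list. A gene that this rule covers is not reported here. The median 3′ UTR length of each list was placed among the medians of 10000 random lists of the same size drawn from the 17457 coding genes. A median below percentile 2.5 or above percentile 97.5 was called beyond the limits, which were set before the percentiles were computed but after the lists' medians had been seen. These percentiles describe the annotation, since genes are not replicates. The interval beside a median is the 95% range over 10000 resamplings of the list's members, and it covers the spread among members only.

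The procedure was tested on a simulated annotation of 2000 genes. It recovered all 2000 3′ UTR lengths and all 200 planted overlaps with their lengths, and reported 0 others. Of 200 random lists of 20 genes, 4 lay beyond the limits. Of 200 lists whose members had been lengthened by 1000 bases, 176 lay above the upper limit. The simulated genes had a single transcript each and evenly spread 3′ UTR lengths. The choice of the longest transcript, skewed lengths and lists of other sizes were therefore not tested, and these rates need not hold for the real lists. The alternatives tried were the other annotation, the median over transcripts, curated (NM) transcripts alone, a background of named genes, genes with a 3′ UTR alone, matching on transcript number, gene bodies or both strands for overlaps, and a minimum of 100 shared bases. Of these, the restriction to genes with a 3′ UTR and the matching on transcript number were chosen after the data were seen. Absent symbols were also looked up as synonyms in a newer RefSeq gene table of assembly GRCg7b, which was used for names only, an alternative also chosen after the data were seen. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9 were used.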

Results

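The study addressed how Hox genes take part in the different shaping of the small and large intestine of the chick. Its design implies these comparisons of single-cell transcriptomes: hindgut against midgut at E14, hindgut against midgut with the empty vector at E15, and midgut with the HOXD13 vector against midgut with the empty vector at E15. Each of the 5 groups holds 1 sample. Doxycycline, which switches on the vector, was given at E8 to the E15 midgut samples with the empty and the HOXD13 vector. The labels give no vector or doxycycline day for the other samples. In the E15 comparison of hindgut with midgut, region therefore cannot be told apart from vector and doxycycline. The values analysed here are the study's gene models, in 2 versions, and not expression itself. No gene can therefore be said to be higher or lower in any sample.

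One version of the gene models contained 3 genes added to those of the chicken genome. These were mScarlet, a red fluorescent protein, with a record of 927 bases, cHoxd13co with 1100 bases, and mNeonGreen.P2A.TetOn with 1749 bases. The last is named for a green fluorescent protein and a doxycycline-dependent activator. The other version contained 1 added gene, EGFP, a green fluorescent protein, with a record of 2903 bases. Each of these genes was a single exon on the plus strand of a contig of its own, starting at position 1. The chicken genes did not differ between versions: 1768359 records were shared line for line, and 9 records of the HOXD13 version and 3 of the EGFP version were not, all of them describing the added genes. The versions shared 23739 genes, of which 17457 had a coding sequence.

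Endogenous HOXD13, a posterior Hox transcription factor, was annotated separately from the HOXD13 transgene. It lay on the minus strand of chromosome 7 from 16324760 to 16327305 in the gg6a annotation, with 1 transcript of 2 exons. The first exon covered 16326637 to 16327305 and the second 16324760 to 16326050. Its coding length was 912 bases with the stop codon, and its 3′ UTR, all in the second exon, was 1040 bases from 16324760 to 16325799. The 3′ UTR made up 53.1% of the 1960 exonic bases. The transgene record was 188 bases longer than the endogenous coding length and had no annotated coding sequence or UTR. The sequence of the transgene was not used here, so how far reads of the transgene and of HOXD13 can be told apart was not measured.

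**Figure D1:**
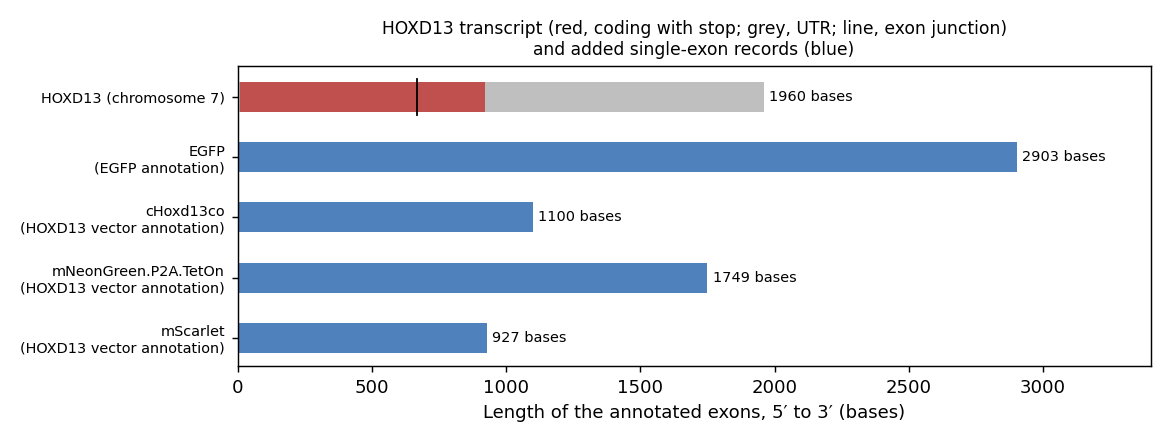
Length in bases of the annotated exons of endogenous HOXD13 and of the added genes, drawn to scale from 5′ to 3′. HOXD13 spans 1960 bases, of which 1040 are 3′ UTR, while cHoxd13co spans 1100 bases in a single exon.

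All 39 Hox genes of the list were annotated, in 4 clusters that each lay on 1 chromosome and 1 strand. HOXA held 11 genes on chromosome 2 (32576149 to 32682123, minus strand), and HOXB held 10 on chromosome 27 (6151195 to 6290582, plus strand). HOXC held 9 genes on chromosome 33 (7539340 to 7663492, plus strand), and HOXD held 9 on chromosome 7 (16253867 to 16327305, minus strand). The clusters spanned 106.0, 139.4, 124.2 and 73.4 kb in that order. In every cluster the 3′ ends of the genes followed each other along the direction of transcription from the highest to the lowest paralogue number. By the outermost annotated 5′ ends, HOXA3 lay upstream of HOXA4, HOXA5 and HOXA6, and HOXD3 upstream of HOXD4. For HOXA3 this rests on a lone predicted model starting at 32632582. Its other models, the curated one included, start at 32600476 or lower, downstream of HOXA4. For HOXD3 it rests on the predicted models starting at 16281680 and 16290827, and its others start at 16272716 or lower, downstream of HOXD4.

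The 3′ UTRs of the Hox genes, where a 3′ assay places its reads, ranged from 26 bases in HOXA2 to 3105 bases in HOXC12, with a median of 778 bases (95% range 553 to 937, 39 genes). That median lay at percentile 47.2 of random lists of coding genes, within the limits. With curated transcripts alone the median was 517 bases (23 genes). The 16 posterior genes of paralogue groups 9 to 13 had a median of 839.5 bases, the 15 genes of groups 4 to 8 one of 636 bases, and the 8 genes of groups 1 to 3 one of 931 bases. By cluster, the median was 884 bases in HOXA, 846.5 in HOXB, 290 in HOXC and 795 in HOXD. Under 100 bases were annotated for 5 of the 39 Hox genes (12.8%), against 12.4% of all coding genes: HOXA2 with 26, HOXC9 with 35, HOXC6 with 38, HOXA13 with 48 and HOXB8 with 52. Of these, HOXC6 rests on predicted records and the other 4 on curated records alone. In paralogue group 13, HOXA13 had 48 bases, HOXB13 302, HOXC13 937 and HOXD13 1040. HOXD10 had 1934 bases, HOXD11 616 and HOXD12 530.

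**Figure D2:**
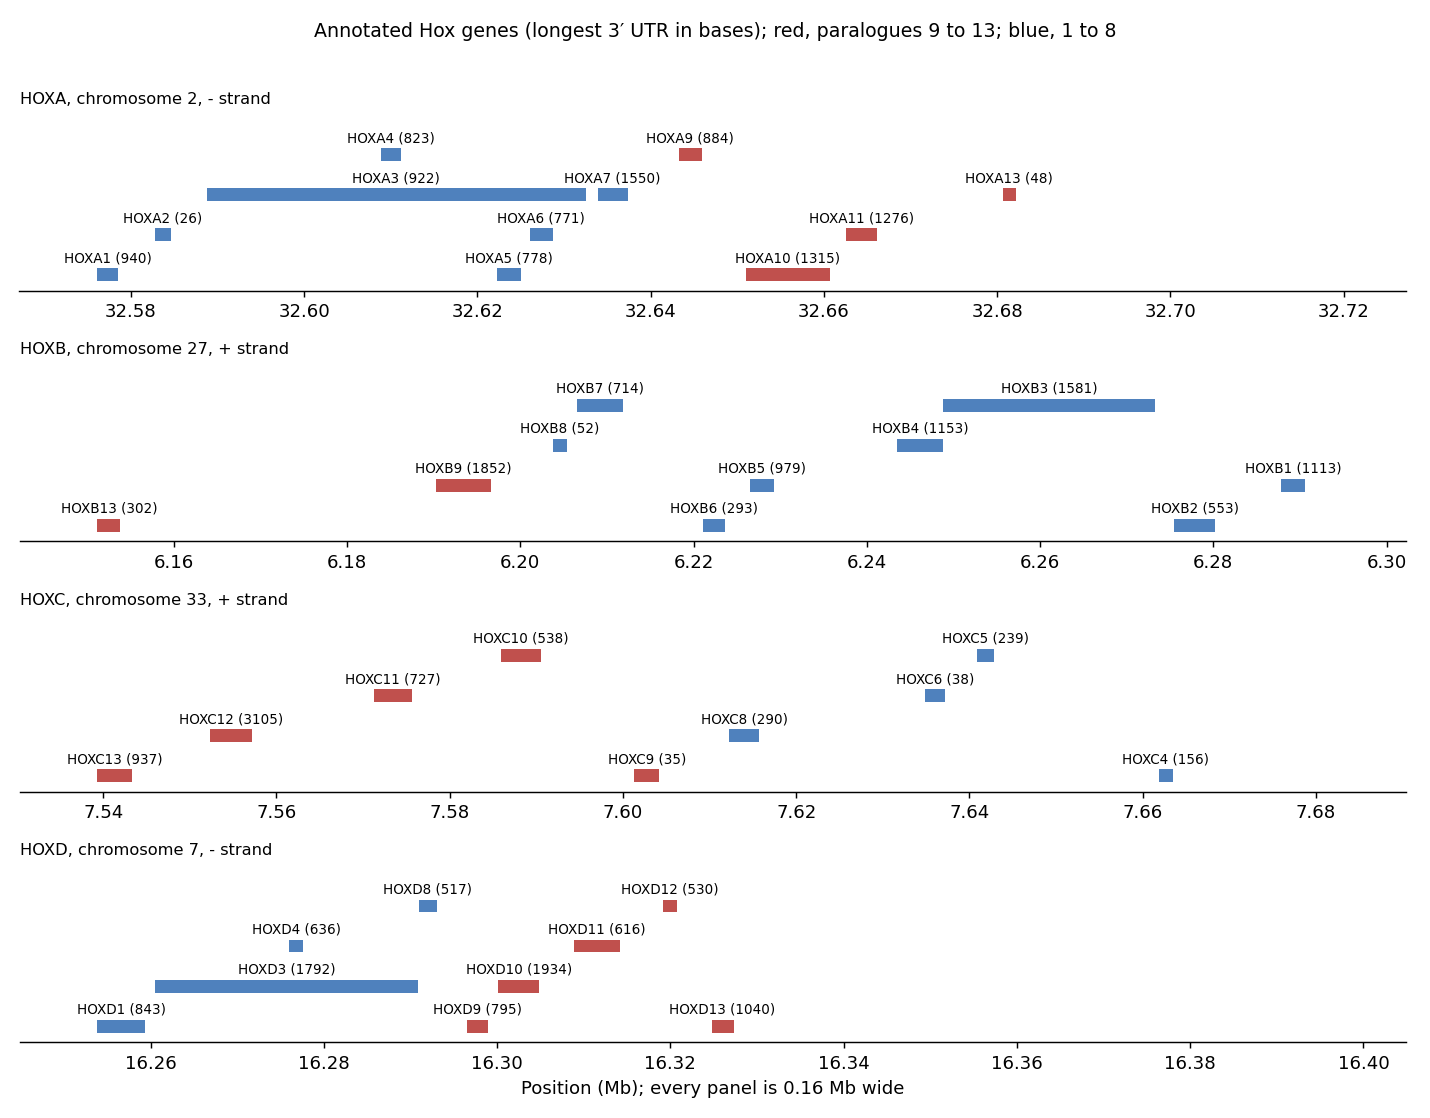
Position in Mb of the annotated Hox genes on chromosomes 2, 27, 33 and 7, drawn to one scale, with bars from the first to the last exonic base, stacked only for legibility, and the longest 3′ UTR in bases after each name. Red bars are paralogue groups 9 to 13, and the shortest 3′ UTRs are those of HOXA2 (26), HOXC9 (35), HOXC6 (38), HOXA13 (48) and HOXB8 (52).

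No Hox gene shared an exonic base with another gene on its own strand, against 7.17% of all coding genes. When introns were included, 6 of the 39 Hox genes overlapped a neighbour on the same strand, against 11.9% of all coding genes. HOXA3 spanned HOXA4, HOXA5 and HOXA6, and HOXD3 spanned HOXD4, in both cases only through their longest predicted models. On either strand, the exons of 7 Hox genes overlapped another annotated gene, namely HOXA10, with its antisense transcript HOXA10-AS, HOXA11, HOXB3, HOXB4, HOXD1, HOXD3 and HOXD10. By outermost annotated ends, some Hox genes ended close to the next gene on the same strand: HOXB4 ended 29 bases before HOXB3, and HOXD8 ended 131 bases before HOXD3. Each distance rests on a lone predicted model of the downstream gene. The other HOXB3 models start at 6262495 or later, and the other HOXD3 models at 16281680 or lower. The HOXB4 model with the longest 3′ UTR (1153 bases) ends at 6246501, before the 6248818 used for the distance. These distances were read from the annotation after its values were seen.

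Of the 209 listed genes, 202 were annotated under the listed symbol. The absent symbols included SMAD2, LTBP3 and LTBP4 of the TGF-beta list, PHOX2A of the enteric neuron list, and GATA1 and HBAD of the blood list. SMAD2, a signal transducer of TGF-beta receptors, was present under the name SMAD2Z on chromosome Z (1515759 to 1555720), with a 3′ UTR of 125 bases. HBAD, an alpha-type globin, was present as HBM on chromosome 14 (12507377 to 12508287), with a 3′ UTR of 46 bases. LTBP3, LTBP4, PHOX2A and GATA1 were not found under a synonym either. All 27 extracellular matrix genes, all 16 BMP genes, all 10 Hedgehog genes and all 18 Wnt genes were annotated, as were all listed markers of gut mesenchyme, smooth muscle, epithelium, endothelium, interstitial cells and mesothelium.

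The listed genes had a median 3′ UTR of 886.5 bases (95% range 787 to 1054, 202 genes), against 796 bases for all coding genes (quartiles 257 and 1929). The median lay at percentile 80.3 of random lists, within the limits. Among the 14 lists, the BMP list alone lay beyond the limits, with a median of 2361 bases (95% range 381 to 3127, 16 genes) at percentile 99.8. Chance would place 0.7 of 14 lists there, and the BMP call was lost when the median over each gene's transcripts was used (1112 bases, percentile 86.5). With curated transcripts alone, the BMP median was 201 bases at percentile 5.13 (15 genes), and the median of all listed genes was 424 bases (154 genes). Within the BMP list, BMPR2, a type II receptor, had 7181 bases and SMAD9 5707, whereas NOG, a secreted BMP antagonist, had 0 and BMP4 201. These genes also differ in their records: BMPR2 and SMAD9 have predicted models besides a curated one, and NOG and BMP4 a curated record alone. The NOG record holds coding sequence only (672 bases), so its 3′ UTR is missing from the annotation.

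The TGF-beta list had a median of 897 bases (percentile 61.4, 18 genes). Its longest 3′ UTRs were those of SKI with 4696 bases and INHBA with 4092, and its shortest those of SMAD3 with 0 and SMAD4 with 36. The record named SMAD4 lay on chromosome 25 (3338469 to 3344036), and its orthology was not checked. The extracellular matrix list had a median of 1008 bases (percentile 75.3, 27 genes), with COL4A1, a basement membrane collagen, at 2980 bases and COL5A1 at 2742. COL1A1, a fibrillar collagen, had 125 bases, and LOX, which cross-links collagen and elastin, had 0. The Hedgehog list (median 978 bases, percentile 63.6, 10 genes) ran from SHH with 41 bases and SUFU with 331 to GLI3 with 4114 and HHIP with 7555. With curated transcripts alone its median was 41 bases at percentile 0.585 (7 genes), below the lower limit. The Wnt list (median 1010.5 bases, percentile 70.3, 18 genes) ran from FZD2 with 176 bases and WNT4 with 185 to TCF7 with 3443 and WNT11 with 5276, and had a median of 493.5 bases with curated transcripts alone (16 genes).

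The epithelium markers had a median 3′ UTR of 443 bases (percentile 13.2, 15 genes), which was within the limits. Of these, 5 were under 100 bases: FABP2, a fatty acid binding protein of enterocytes, with 0, SOX9 with 39, KRT18 with 58, APOA4 with 60, and VIL1, the microvillus protein villin, with 72. KRT18, APOA4 and VIL1 were named after their values were seen. The longest were those of GATA4 with 4227 bases and LGR5 with 2863. The enteric neuron and glia markers had a median of 584 bases (percentile 30.8, 11 genes), with TUBB3 at 0, HAND2 at 10, SOX10 at 1789 and ELAVL4 at 3129. The gut mesenchyme markers had a median of 1220 bases (percentile 80.8, 12 genes), from BARX1 with 354 and NKX2-3 with 389 to PDGFRA with 3237 and PDGFRB with 4050. The smooth muscle markers had a median of 955 bases (percentile 63.2, 12 genes), from ACTG2, the enteric smooth muscle actin, with 96 and CNN1 with 223 to MYOCD with 1955 and SYNPO2 with 3810. With curated transcripts alone, the medians were 290.5 bases for enteric neurons and glia (10 genes), 423.5 for gut mesenchyme (8 genes) and 546 for smooth muscle (9 genes), all at percentiles within the limits.

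The endothelium markers had a median of 1022.5 bases (percentile 64.8, 8 genes), from FLT1 with 22 and EGFL7 with 317 to CDH5 with 2156 and FLT4 with 3649. The blood and immune markers had a median of 1111 bases (percentile 69.4, 8 genes), from HBA1 with 99 and HBBA with 106 to LCP1 with 1319 and RUNX1 with 5170. The mesothelium markers had a median of 970 bases (percentile 59.9, 5 genes), from UPK3B with 0 and MSLN with 555 to WT1 with 1238 and LRRN4 with 1250. With curated transcripts alone, the medians were lower, at 466.5 bases for blood and immune cells (8 genes) and 485 for mesothelium (2 genes). For interstitial cells the curated median was 1784.5 bases (2 genes). For endothelium it was higher, at 1259 bases (5 genes). With the median over transcripts, the list medians were 676 bases for endothelium and 619 for mesothelium. The interstitial cell markers KIT, ANO1 and ETV1 had 2163, 2387 and 8455 bases. Over all lists, 22 of 202 genes (10.9%) had a 3′ UTR under 100 bases, against 2170 of 17457 coding genes (12.4%).

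**Figure D3:**
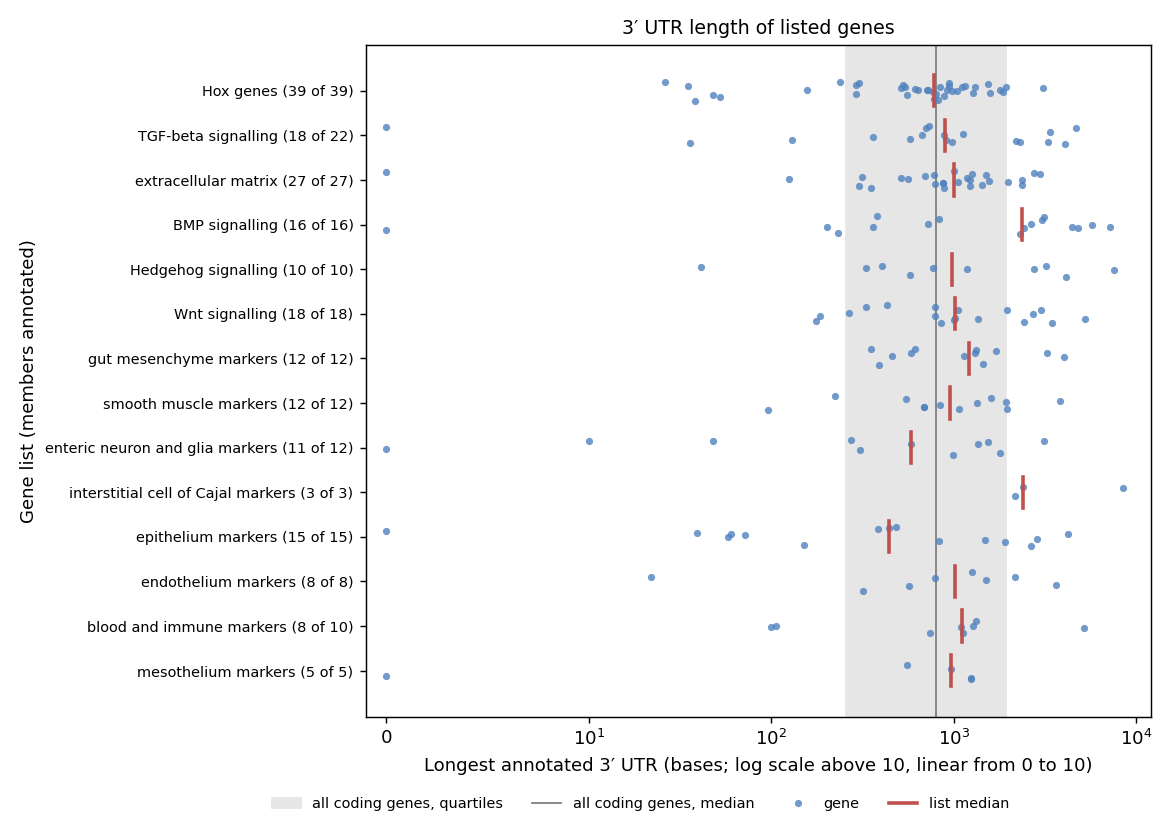
Longest annotated 3′ UTR in bases of each listed gene (points) and the median of each list (red lines), on an axis that is logarithmic above 10 bases. Grey marks the median (796 bases) and the quartiles (257 and 1929 bases) of all 17457 coding genes, and the BMP list has the median 2361.

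Same-strand exon overlap with another gene affected 5 of the 202 listed genes, against 7.17% of all coding genes. FLT4, a receptor of lymphatic endothelium, shared 954 bases with RNF130, and SMAD1, a BMP signal transducer, shared 894 bases with MMAA. In both genes the shared bases fell entirely within the listed gene's own 3′ UTR. THY1 shared 110 bases of its 3′ UTR with the microRNA gene MIR1466. LAMC1, a laminin chain, shared 593 bases with NPL, and SRF, a transcription factor of muscle genes, shared 127 bases with MIR6542, in both cases outside the 3′ UTR.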

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

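The tests with synonyms, with genes that have a 3′ UTR and with matching on transcript number were chosen only after the data were seen. The counts of listed genes (202) and of Hox genes (39) were the same in the EGFP version, that of differing records (12) was the same by position alone, and 204 listed genes were found with synonyms. The annotations carry no synonym field, so the synonym match planned for them gave no value. The 5 listed genes with an exon overlap stayed 5 with at least 100 shared bases and in the EGFP version, and became 14 with gene bodies and 36 with exons on either strand, both of which add bases by construction. The median 3′ UTR of the listed genes (886.5 bases) was 786.5 with the median over transcripts and 424 with NM transcripts alone, which left 154 genes. The cause was not tested. Its percentile stayed within the limits under all alternatives, from 28.1 with NM transcripts to 92.4 with matching on transcript number. The percentile of the BMP list fell to 5.13 with NM transcripts alone, on the other side of the middle. Its curated records had shorter 3′ UTRs as a set, and the reason for that was not tested. Of the single lists' results, 9 with NM transcripts and 1 with the median over transcripts left the median's 95% range or changed their side of a limit, and other medians also moved, within that range. The annotations hold no read counts, so depth limits nothing here and error of measurement was not assessed.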

Other observations

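The tests on short Hox 3′ UTRs and on the BMP list, the split of the short Hox genes by kind of record, and the limits of 100 and 1000 bases were chosen only after the lengths and kinds of record were seen. Of the 8 Hox genes with both a curated (NM) and a predicted (XM) record, the NM record had a shorter 3′ UTR than the longest XM record in 7. HOXD8 had equal ones. HOXA3 and HOXA10 had no 3′ UTR in their NM record and 922 and 1315 bases in the longest XM record, HOXB3 had 250 against 1581, HOXB4 had 154 against 1153, and HOXD11 had 72 against 616.

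The share of Hox genes with under 100 bases of 3′ UTR (5 of 39, 12.8%) was close to that of all coding genes (2170 of 17457, 12.4%), so short 3′ UTRs do not set the Hox genes apart, and what follows concerns these 5 records alone. A candidate explanation for them is that curated records are cut short. It cannot apply to HOXC6 with 38 bases, which rests on predicted records only. That was known before the test was chosen, so the test excludes nothing for the other 4. For HOXA2, HOXA13, HOXB8 and HOXC9, which have curated records alone, the explanation stays open. Outside the Hox genes, the curated record had the shorter 3′ UTR in 66.6% of 3304 genes with both kinds (exact 95% interval 65.0 to 68.3). This share cannot decide it, since the longest of several predicted records can exceed a curated one through their number alone. Genes with both kinds may also be ones whose records disagree. Among Hox genes, 4 of the 5 short ones and 11 of the other 34 had curated records alone (Fisher's exact test, two-sided p = 0.062). Hox genes with curated records alone also lack predicted models from which a longer 3′ UTR could be taken. For the 5 short Hox genes, the next same-strand gene lay at a median of 4245 bases (1139 to 14595). These distances all exceed 1000 bases, the limit used for a close neighbour. That limit was chosen after the lengths were seen, and genes on the other strand were left out. Most other Hox genes also lay beyond the limit. The test therefore cannot decide whether a neighbouring gene close downstream accounts for the short 3′ UTRs. A truly short 3′ UTR was not tested, since that needs reads.

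The long median 3′ UTR of the BMP list stayed above the upper limit when random lists were matched on the number of transcripts (percentile 99.5), so the number of annotated transcripts does not account for it. The percentile fell to 86.5 when each gene was given the median over its transcripts, as a dependence on the longest transcript model predicts. This is the same value that showed the loss of the BMP call, and the prediction was written afterwards, so it adds no separate support. With NM transcripts alone the percentile fell to 5.13, and the median fell from 2361 to 201 bases. That setting left out only BMP7 (2637 bases), which moves the median only to that of BMP5 (2304 bases). The fall therefore lies in shorter 3′ UTRs in the curated records of the other 15 genes. It is not owed to the smaller background (6044 genes) alone. A value of 201 bases also lies below the lower quartile of all coding genes (257 bases). Why the curated records were shorter was not tested. A biological difference in BMP genes stays untested.

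Whether the listed genes as a whole differed in 3′ UTR length from other coding genes was also asked, and their median lay within the limits. The technical explanations prepared for such a difference were the number of annotated transcripts and unnamed genes in the background. They gave percentiles of 92.4 and 33.1, but with no difference called beyond the limits neither could be decided.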
